A study of Homo sapiens with 8 samples.

How the data were processed

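RNA-seq was measured in 8 libraries of EPC2-hTERT cells, 4 CTRL and 4 miR-155OE. Per the labels' protocols the cells grew on inserts with 0.4 µm pores for 2 days, then for 5 days in medium with 1.8 mM calcium, and were then raised to the air-liquid interface. Total RNA was extracted and libraries were made with a NEBNext Ultra kit, per the labels. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 and the build GRCh38, and state no strand setting, options or annotation release.

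The deposited raw counts are whole numbers per Ensembl gene, per the file headers, with the name, position, strand, length and type of each gene beside them. A second deposited table holds a normalised signal per library, which from the values is the raw count divided by 1 size factor per library, and the mean signal of each group. It also holds the authors' log2 fold change (miR-155OE over CTRL) and the authors' p-value with its adjusted p-value, which is 1 for 8913 genes. The raw counts were used for all fits. The authors' table was used only for its calls and for its values of named genes.

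Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr kept 15135 genes, TMM factors scaled the libraries, and the quasi-likelihood F test compared miR-155OE with CTRL on group alone, with Benjamini-Hochberg adjustment at a false discovery rate of 0.05. CPM values use the TMM-scaled library sizes. A floor of 3 reads was used for genes with 0 reads, and confidence intervals are at 95%. Each SE of an edgeR log2 fold change was derived from that fold change and its F statistic, and the intervals from the SE. They therefore restate the test and are not a separate measure of precision. Other tools were limma 3.58.1 (camera, fry, voom), DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene positions and types came from the deposited raw count file, and 3′ UTRs, transcript lengths and GC content from GENCODE release 29 on GRCh38.

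The labels number libraries 1 to 4 in each group without saying what a number shares. Over 10266 genes, the deviations of same-numbered CTRL and miR-155OE libraries from their group means correlated across genes at 0.578, 0.497, 0.184 and 0.607 for numbers 1 to 4, so the numbers were taken to pair the samples. Genes are not independent replicates. For 3 of the 4 numbers the own pair was the best match, and for number 3 another miR-155OE library correlated more (0.203). The fit with the replicate number as a block is given beside a result where it changes a call or moves a count by over 1.5 times.

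The design, the 24 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for those alternatives said to be chosen after seeing the data. The rule named MIR155HG, CLDN7 and HIF1A, then the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean CPM of at least 1 and non-overlapping groups, then the 5 lowest p, then the 3 members of each list with the lowest p. Further list members given as examples, genes that overlap named genes and MIR155 were chosen after their values were seen.

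The 24 lists were tight junction, adherens junction and desmosome, squamous differentiation, proteases and inhibitors, basal keratinocyte, mesenchymal, hypoxia, reported miR-155 targets, type I interferon, inflammatory and NF-kB, IL-13 and eosinophilic esophagitis, S phase, G2/M, cholesterol synthesis, unfolded protein and integrated stress, p53 targets, TGF-beta and SMAD targets, immediate early, antigen presentation, simple and columnar epithelium, immune cell, endothelial with neural and melanocyte, mitochondrially encoded, and ribosomal protein genes. The 23 lists with at least 5 tested members were tested by camera, a competitive test, with a preset correlation of 0.01 and with an estimated one. They were also tested by fry, whose directional p asks whether a list's genes move one way on balance and whose mixed p asks whether they move in either direction, neither of which compares the list with other genes. A further pair of lists, epidermal and mucosal, was written after the squamous result had been seen, from genes not in the other lists, and 2 genes whose values had already been seen were left out before the test.

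Matches to bases 2 to 8 of miR-155-5p (AGCATTA, with or without a following A, or its last 6 bases followed by A) were searched in the longest annotated 3′ UTR of each gene. Their shift was compared with that of 419 scrambled heptamers and with 10000 sets of genes lacking a site matched on UTR length and GC content. Position medians used genes with a mean log2 CPM of at least 2, in bins of 10 Mb holding at least 10 genes, with the arms of chromosome 8 parted at 45 Mb.

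The methods were tested on simulated data, drawn 3 times for 15135 genes from the means and sizes of these libraries. In the comparison of miR-155OE with CTRL so simulated, edgeR on group alone recovered 44.7% of genes changed 1.5-fold, 76.7% at 2-fold, 88.7% at 3-fold and 94.7% at 4-fold, and called 37 of 44715 unchanged genes. With the replicate block it recovered 36.7%, 74%, 84.7% and 94% and called 51. The simulated libraries held no shared effect of the replicate number, and genes were drawn independently. These figures therefore do not show how the blocked fit behaves on paired samples. A simulated shift of −0.1 in the genes with an 8-base seed match was called in 3 of 3 runs. That shift is larger than the one observed (−0.0170), and a shift of the observed size was not simulated.

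Alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), other filters, protein-coding genes alone, DESeq2, limma-voom, the replicate block, stricter thresholds, and each library or number left out in turn. All 35 splits of the libraries into 4 and 4 were refitted. No library was excluded.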

Results

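RNA was sequenced from EPC2-hTERT cells, a telomerase-immortalised human esophageal epithelial line, grown at the air-liquid interface, where they stratify into a layered epithelium. The design held 2 groups. The first comprised 4 control libraries (CTRL) and the second comprised 4 libraries of a stable line carrying a lentiviral miR-155-5p construct (miR-155OE). Total counts ranged from 33.4 to 52.7 M (mega) per library, with a mean of 40.0 ± 8.79 M (SD, n = 4) in CTRL and 36.4 ± 3.21 M (SD, n = 4) in miR-155OE. Mitochondrially encoded genes took 2.04 ± 0.727% of the counts in CTRL and 1.79 ± 0.846% in miR-155OE (SD, n = 4 each). Of the genes listed, 15135 had enough reads to be tested. The labels number the libraries 1 to 4 in each group and do not say that they are separate cultures. The p-values therefore measure the spread between these samples, which may be technical. Pairs of libraries within a group had a chi-square per degree of freedom of 15.8 to 82.5, where counting error alone gives about 1. These values argue against repeat sequencing of 1 library, but do not tell separate cultures from separate preparations of 1 culture. Floors given in reads cover counting error only, and intervals from the fits cover the spread between these libraries.

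The comparison of miR-155OE with CTRL asked how excess miR-155-5p altered the epithelium and its barrier genes. KRT1, the keratin of suprabasal epidermal cells, rose from 951 ± 400 CPM (counts per 1 M counts of the library) in CTRL to 6332 ± 2844 CPM in miR-155OE (SD, n = 4 each), a log2 fold change of 2.73 (SE 0.39, edgeR adjusted p = 0.00685). The desmosomal cadherins of differentiated keratinocytes rose with it: DSC1 from 11.8 ± 7.97 to 169 ± 115 CPM and DSG1 from 319 ± 74.1 to 990 ± 426 CPM (SD, n = 4 each). CLDN7, the tight junction claudin named in the title of the series, stood at 46.2 ± 21.5 CPM in CTRL and 30.7 ± 19.0 CPM in miR-155OE (SD, n = 4 each) and did not pass the test fitted on group alone (log2 fold change −0.59, SE 0.40, edgeR adjusted p = 0.469). With the replicate number as a block, CLDN7 was lower in 4 of 4 pairs and passed it (log2 fold change −0.66, SE 0.08, adjusted p = 0.00242). Genes of the short arm of chromosome 8 were lower and genes of its long arm were higher, together, in all 4 miR-155OE libraries.

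By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 488 of the 15135 genes (3.22%) changed: 329 rose and 159 fell in miR-155OE. With the replicate block, 1125 genes rose and 783 fell, 1908 in all, and these included all 488. At an unadjusted p under 0.05 there were 2925 genes. The groups did not overlap in 1728 genes (11.4%), where chance gives 2.86%. The first principal component (PC1), the main axis of variation between the libraries, held 50.2% of the variance and did not part the groups. On PC1 miR-155OE replicate 2 (−4.45) lay below CTRL replicate 4 (−2.33). CTRL replicates 1, 2 and 3 lay at −17.5, −19.0 and −12.5, and miR-155OE replicates 1, 3 and 4 at 10.9, 26.7 and 18.2. The authors' deposited table called 1208 genes at its adjusted p, 774 higher and 434 lower, and included all 488 in the same direction. The count moved with the libraries used: 156 genes without CTRL replicate 1, 203 without CTRL replicate 2, 129 without CTRL replicate 3, 125 without miR-155OE replicate 1, 173 without miR-155OE replicate 3, 321 without miR-155OE replicate 4 and 1274 without miR-155OE replicate 2.

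The overexpressed microRNA itself could not be read from these libraries. Its host gene MIR155HG (ENSG00000234883; GRCh38, chromosome 21, 25561909 to 25575168) and the hairpin gene MIR155 (25573980 to 25574044) had 0 reads in all 8, where 3 reads would be 0.0569 to 0.0897 CPM, so these counts gave no check of the labels. CLDN7 (ENSG00000181885) lies on chromosome 17 at 7259903 to 7263983. Its 95% interval in the fit on group alone ran from −1.47 to 0.29 on the log2 scale. The largest single-library influences on the CLDN7 log2 fold change were miR-155OE replicate 2 (−1.11 without it, adjusted p = 0.0537) and CTRL replicate 2 (−0.22 without it, adjusted p = 0.833). The annotated 3′ UTR of CLDN7, 583 bases long, held 0 sites for the miR-155-5p seed. CLDN7 overlaps ELP5 on the opposite strand (log2 fold change 0.11, adjusted p = 0.508), and the counting is not stated to use strand, so reads of the overlap cannot be told apart. HIF1A, the oxygen-regulated transcription factor (ENSG00000100644; chromosome 14, 61695513 to 61748259), stood at 387 ± 50.9 CPM in CTRL and 381 ± 31.0 CPM in miR-155OE (SD, n = 4 each; log2 fold change −0.02, adjusted p = 0.935).

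**Figure D1:**
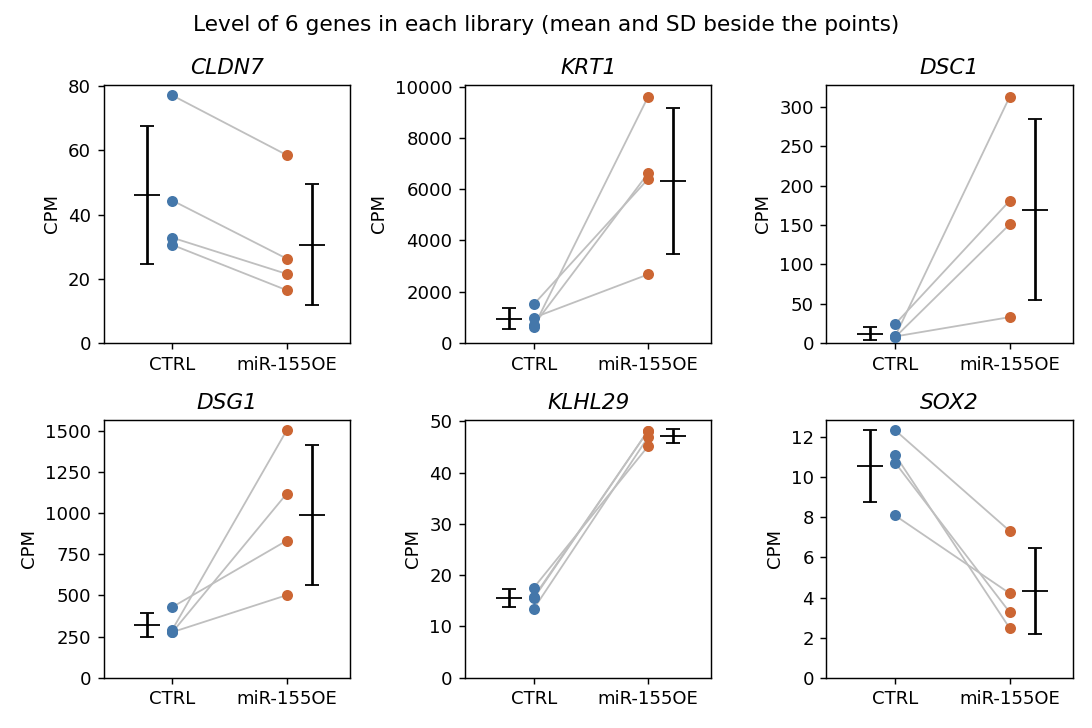
Level in CPM (vertical axis, from 0) of CLDN7, KRT1, DSC1, DSG1, KLHL29 and SOX2 in each of the 4 CTRL and 4 miR-155OE libraries, with grey lines joining libraries of the same number and bars giving the mean and SD. KRT1, DSC1, DSG1 and KLHL29 lie higher in every miR-155OE library than in every CTRL library, whereas the CLDN7 values of the groups overlap and each line falls.

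Among the largest rises, MYL4, an atrial and embryonic myosin light chain (ENSG00000198336; chromosome 17, 47200446 to 47223679), had 0 reads in the CTRL libraries and 110 to 175 reads in each miR-155OE library (4.15 ± 1.05 CPM, SD, n = 4), at least 53.8-fold higher against a floor of 3 reads per library. GPRC5C, an orphan receptor, went from 7 reads in all CTRL libraries to 302 in the miR-155OE libraries (log2 fold change 5.44, and 6.75 without CTRL replicate 2, which held most of the CTRL reads). Its CTRL mean, 0.0483 CPM, lay below the level of 3 reads in a library, so the size of its fold is uncertain. CHP2, CCDC3, RPS6KA6, DEGS2, NELL2 and SOST rose by 2.46 to 3.33 on the log2 scale. Of these, DEGS2 makes the phytoceramides of the skin barrier and SOST encodes a WNT antagonist of bone. The lowest p belonged to KLHL29 (ENSG00000119771; chromosome 2, 23385217 to 23708611), at 15.5 ± 1.68 CPM in CTRL and 47.1 ± 1.44 CPM in miR-155OE (SD, n = 4 each; log2 fold change 1.60, SE 0.08, edgeR adjusted p = 3.14e-05). WWC3 and H6PD, the latter an enzyme of the endoplasmic reticulum pentose phosphate pathway, rose by 1.40 and 1.49. NELL2 lost its call without any library but miR-155OE replicate 2 (highest adjusted p = 0.133), and its log2 fold change was 1.84 without miR-155OE replicate 1. CHP2 lost its call without CTRL replicate 3 (adjusted p = 0.0507), and its log2 fold change was 4.20 without CTRL replicate 2.

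Among the largest falls were the noncoding or unclassified transcripts UCKL1-AS1 (log2 fold change −1.39), AC016586.1 (log2 fold change −4.01), AC138028.6 (−2.89), AC114341.1 (−2.89), AC037459.3 (−2.12), AC131212.3 (−2.12) and AL731571.1 (−1.67). All but AC114341.1 overlap a protein-coding gene, and their reads cannot be told apart from that gene's in the overlap: UCKL1 (−0.19), ZBTB7A (0.08), CTU2 (0.08), FBRSL1 (0.25) and CTBP2 (−0.14) did not pass the test, whereas CCAR2 on chromosome 8 fell with AC037459.3 (−0.50). TIAF1, which lies within MYO18A, fell by 1.61 on the log2 scale. PLD5, of the phospholipase D family, fell by 1.62 and WIPF1, a binding partner of the actin regulator WASP, by 1.44. Calls were lost for PLD5 without CTRL replicate 1 or 3 or miR-155OE replicate 1 or 3 (highest adjusted p = 0.0655), for UCKL1-AS1 without CTRL replicate 3 (0.0507) or miR-155OE replicate 1 (0.0513), and for WIPF1 without each library but miR-155OE replicates 2 and 4 (highest adjusted p = 0.102).

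The squamous differentiation list split in opposite directions. Of its 61 tested members, 3 rose, 2 fell and 56 did not pass over all genes, while adjusted over the list alone 10 rose and 5 fell. KRT1, LCE1A (log2 fold change 1.16), a late cornified envelope protein, and CASP14 (1.33), the caspase of the cornifying layer, rose. KRT78 (−0.68), a keratin of esophageal suprabasal cells, and RPTN (−0.51), a cornified envelope precursor, fell. Under the block by replicate number 18 members rose and 13 fell. The risers then included the epidermal genes KRT10 (1.06, SE 0.18), KRTDAP (1.43, SE 0.14) and LCE2A (1.83, SE 0.43). Falling members then included KRT4 (−3.00, SE 0.51), KRT13 (−2.27, SE 0.49), CRNN (−1.41, SE 0.37) and SPRR3 (−1.92, SE 0.49), the keratins and envelope proteins typical of moist esophageal mucosa. None of these 7 passed on group alone (edgeR adjusted p = 0.0608 to 0.251). As a whole the list was not called by camera, which tests whether a list's genes move differently from the other genes (adjusted p = 0.723). Without 1 library LCE1A reached an adjusted p of 0.112 and KRT78 of 0.127.

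Desmosome and adherens junction genes numbered 24 tested: 2 rose, DSC1 (log2 fold change 3.84, SE 0.63, edgeR adjusted p = 0.0136) and DSG1 (1.64, SE 0.29, adjusted p = 0.0188), and 22 did not pass. The count was also 2 adjusted over the list alone. The list's median was −0.04 and its mean 0.17, and camera's direction was down (adjusted p = 0.949). DSG2, the desmoglein of basal and simple epithelia, fell only with the replicate block (−0.32, SE 0.08, adjusted p = 0.0271). DSC1 lost its call without CTRL replicate 1 (adjusted p = 0.0504) or 3 (0.0629), with a log2 fold change of 4.43 without CTRL replicate 4, and DSG1 without CTRL replicate 1 (0.0616), 2 (0.0572) or 3 (0.0702) or miR-155OE replicate 1 (0.0593). DSC1 lies on chromosome 18 at 31129236 to 31162856 and KRT1 on chromosome 12 at 52674736 to 52680407 (GRCh38).

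Of 29 tested tight junction genes, 1 fell and 28 did not pass, and the same 1 passed adjusted over the list alone. The gene that fell was PALS1 (listed as MPP5), a polarity scaffold that overlaps ATP6V1D (0.04), at 41.1 ± 3.10 CPM in CTRL and 28.2 ± 4.46 CPM in miR-155OE (SD, n = 4 each; log2 fold change −0.54, SE 0.11). In the blocked fit 5 fell: PALS1, CLDN7, the cytoplasmic adaptor CGNL1 (−0.82, SE 0.11), TJP3 (−0.52, SE 0.10) and the tricellular junction receptor LSR (−0.22, SE 0.05). The abundant claudins CLDN1 (0.18, adjusted p = 0.517) and CLDN4 (−0.05, adjusted p = 0.865) did not pass. Camera did not call the list on group alone (adjusted p = 0.0866) and called it lower with the replicate block (adjusted p = 0.0124, and adjusted p = 0.557 with an estimated correlation). The call of PALS1 was lost without each library except CTRL replicate 4 and miR-155OE replicate 2 (highest adjusted p = 0.0974).

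Of 29 tested proteases and inhibitors 2 rose, both kallikreins, which are proteases of epithelial shedding: KLK10 from 369 ± 51.8 to 601 ± 41.3 CPM (log2 fold change 0.70) and KLK5 from 165 ± 34.8 to 304 ± 52.7 CPM (0.88; SD, n = 4 each), and 27 did not pass. Adjusted over the list alone 3 rose and 2 fell, and with the replicate block 8 rose and 3 fell, the latter including SPINK7, a protease inhibitor of the esophagus (−1.81, SE 0.32). Of 25 tested basal keratinocyte genes, EGFR rose (0.60, SE 0.10), SOX2, a transcription factor of the foregut, fell (−1.29, SE 0.28) and 23 did not pass. There 2 rose and 3 fell adjusted over the list alone. In the blocked fit 2 rose and 7 fell, among them the laminin chains LAMA3 (−0.54) and LAMB3 (−0.49). KLK5 lost its call without CTRL replicate 1 (adjusted p = 0.0600) or miR-155OE replicate 1 (0.0657) or 3 (0.0603), and SOX2 without each library except CTRL replicate 4 and miR-155OE replicate 2 (highest adjusted p = 0.114).

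**Figure D2:**
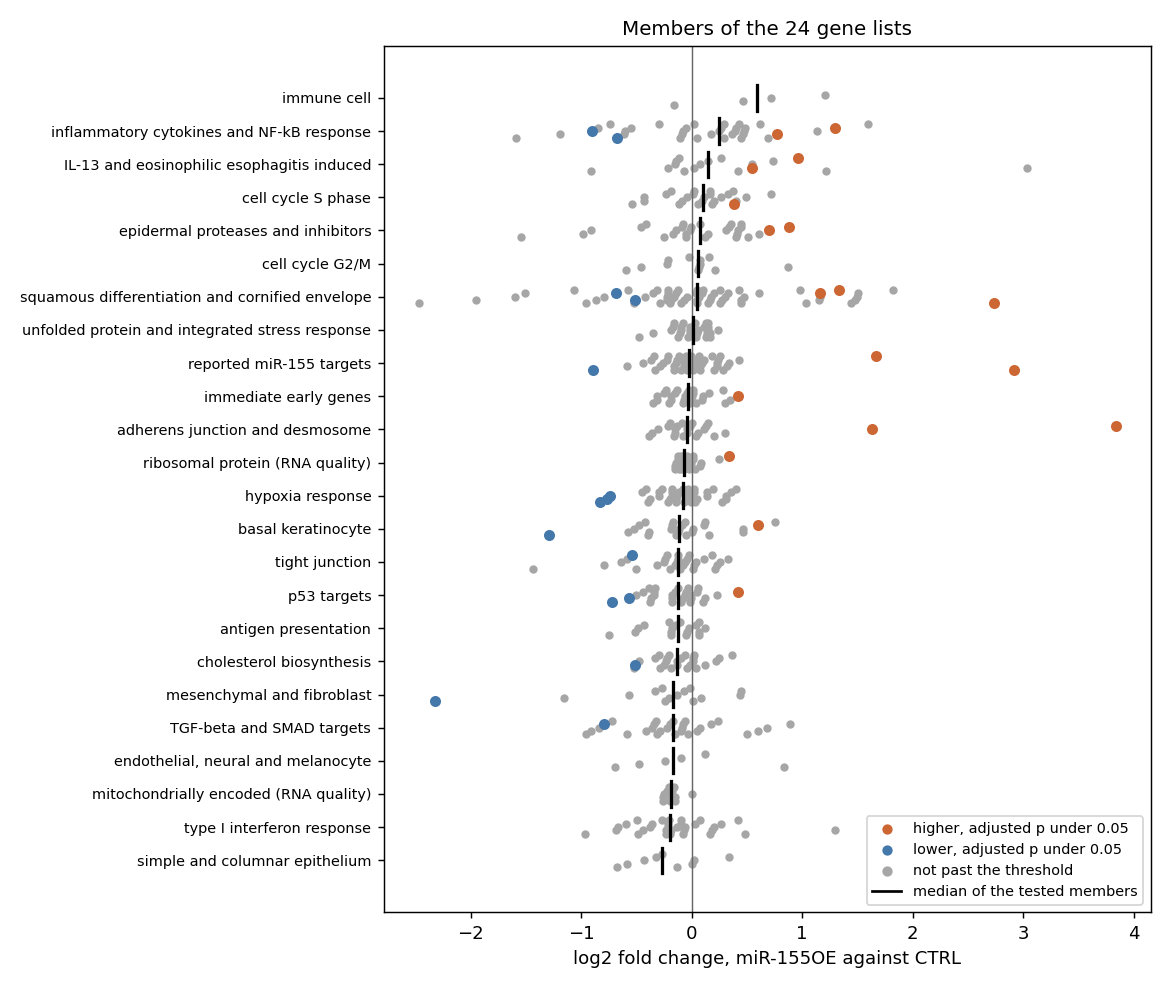
Log2 fold change of each tested member of the 24 lists (horizontal axis), with the list median as a black bar and members past the threshold in colour. The squamous differentiation list holds members on each side of 0, and DSC1 of the junction list lies farthest to the right at 3.84.

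Cytokine genes moved both ways. Of 35 tested inflammatory and NF-kB genes, IL36RN, an antagonist of IL-36 signalling, and PTGS2, the inducible cyclooxygenase, rose (log2 fold change 1.29 and 0.77), IL1B and IL18 fell (−0.90 and −0.67), and 31 did not pass. Adjusted over the list alone 7 rose and 3 fell, and with the replicate block 6 rose, IL36G among them (1.45), and 4 fell. Of 17 tested genes of IL-13 and eosinophilic esophagitis, 2 rose, the chloride channel ANO1 (0.96, SE 0.19) and the cadherin CDH26 (0.55, SE 0.11), and 15 did not pass. There were 3 that rose adjusted over the list alone. The blocked fit raised this to 6, ARG1 with the largest fold change (3.00, SE 0.17), and camera called the list higher (adjusted p = 0.00579, and adjusted p = 0.414 with an estimated correlation), which it did not on group alone (adjusted p = 0.119). Without 1 library, ANO1 reached an adjusted p of 0.0820, CDH26 0.0889, IL36RN 0.0852 and IL18 0.119.

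Of 40 tested hypoxia genes, 3 fell and 37 did not pass: PLOD2, a collagen lysyl hydroxylase (log2 fold change −0.83, SE 0.12), the glycolytic kinase PGK1 (−0.74, SE 0.12) and ANKRD37 (−0.77, SE 0.16). PGK1 overlaps ATP7A (0.32) and ANKRD37 overlaps UFSP2 (−0.04), whose reads cannot be told apart from theirs where they overlap. The same count of 3 held adjusted over the list alone, and with the replicate block 3 rose and 5 fell. Camera did not call the list on group alone (adjusted p = 0.0866) and called it lower with the replicate block (adjusted p = 0.0352, and adjusted p = 0.629 with an estimated correlation). PGK1 lost its call without miR-155OE replicate 3 (adjusted p = 0.0545) and ANKRD37 without CTRL replicate 1, 2 or 3 or miR-155OE replicate 1 or 3 (highest adjusted p = 0.103).

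Camera called 2 of the 23 lists it tested, each lower in miR-155OE: p53 targets (adjusted p = 0.00307, and adjusted p = 0.199 with an estimated correlation) and TGF-beta and SMAD targets (adjusted p = 0.0214, and adjusted p = 0.421 with an estimated correlation). Of 29 tested p53 targets, the death receptors TNFRSF10B (log2 fold change −0.72, SE 0.09) and TNFRSF10A (−0.57, SE 0.10) fell, the antiproliferative gene BTG2 rose (0.42, SE 0.10) and 26 did not pass. Both death receptors lie on the short arm of chromosome 8, where TNFRSF10B overlaps RHOBTB2 (−0.48), and without chromosome 8 genes the list was still called (adjusted p = 0.0179). Adjusted over the list alone 2 rose and 8 fell, and with the replicate block 10 fell, including FAS (−0.44) and GDF15 (−0.34). Of 29 tested TGF-beta and SMAD targets, 1 fell and 28 did not pass. Adjusted over the list alone 3 rose and 8 fell, and with the replicate block 3 rose, MMP1 among them (0.83), and 12 fell, including TGFB2 (−0.99) and THBS1 (−0.95). Fry, which tests whether the genes of a list move one way on balance, called only p53 targets (adjusted p = 0.00814), and its mixed form, which tests for change in either direction, called 14 lists. TNFRSF10A lost its call without CTRL replicate 2 or 3 or miR-155OE replicate 1 or 3 (highest adjusted p = 0.0660).

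Chromosome 8 departed from the rest of the genome. Among genes above 4 CPM, the 123 genes of the short arm (8p) had a median log2 fold change of −0.36, with 97.6% lower, and the 231 genes of the long arm (8q) had a median of 0.27, with 91.8% higher. Per library, the 8p median against the CTRL mean was 0.01 ± 0.02 in CTRL and −0.39 ± 0.18 in miR-155OE, and the 8q median was 0.00 ± 0.03 and 0.28 ± 0.11 (SD, n = 4 each; exact permutation test, two-sided, p = 0.0286 for each arm, the smallest that 4 against 4 allows). The arms were picked from these same libraries after their values were seen, and the p is not adjusted for that choice. In the miR-155OE libraries 1 to 4 the 8p medians were −0.49, −0.21, −0.58 and −0.28, and the 8q medians were 0.32, 0.17, 0.41 and 0.22. In bins of 10 Mb with at least 10 genes, 5 bins of chromosome 8 lay below the lowest of any other chromosome (−0.22) and 8 lay above the highest (0.12). Chromosome 8 held 83 of the 488 calls (17.0%) and 3.51% of the genes tested, and the 33 calls on 8p were all lower. In the blocked fit it held 231 of the 1908 calls (12.1%), and 85 of the 87 calls on 8p were lower. The S-phase helicase subunit MCM4 (0.38) and the ribosomal protein RPL7 (0.34), which overlaps RDH10 (0.37), rose and lie on 8q.

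**Figure D3:**
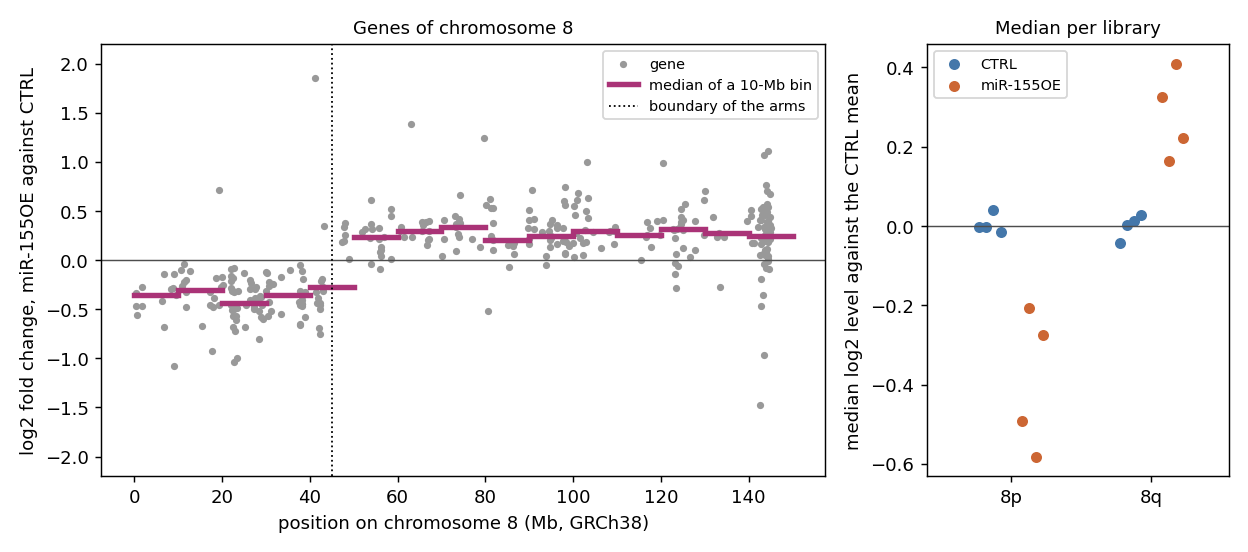
Left, log2 fold change of the genes of chromosome 8 by position (Mb, GRCh38), with the median of each 10 Mb bin as a bar and the boundary of the arms dotted. Right, the median log2 level of 8p and of 8q genes against the CTRL mean in each library, where the 4 miR-155OE libraries lie from −0.58 to −0.21 on 8p and from 0.17 to 0.41 on 8q.

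Reported miR-155 targets did not fall as a list. Of 46 tested, E2F2 (log2 fold change 1.67, SE 0.29) and PALD1 (2.92, SE 0.61) rose, the homeobox gene MEIS1 fell (−0.89, SE 0.21) and 43 did not pass, with the same 2 and 1 adjusted over the list alone. PALD1 lay near the floor in CTRL, at 0.156 ± 0.137 CPM against 1.15 ± 0.590 CPM in miR-155OE (SD, n = 4 each). In CTRL replicates 1 and 3 it was below the level of 3 reads, so the size of its fold is uncertain. Blocked by replicate number 6 rose and 9 fell, the latter including CLDN7, INPP5D (−0.26) and TCF4 (−0.35). The list's median was −0.03, its mean 0.06 and camera's direction down (adjusted p = 0.949). Across all genes, 579 of 12507 with an annotated 3′ UTR carried the 8-base seed match AGCATTAA, and their median log2 fold change differed by −0.0170 from that of the 10323 genes with no match, with 13 of them higher and 13 lower past the threshold, and 43 higher and 49 lower in the blocked fit (exact permutation test over libraries, two-sided, p = 0.229). The share lower past the threshold was 2.25% of the genes with the 8-base match and 0.940% of those with none, and 8.46% and 5.35% in the blocked fit, a difference that was not tested. For the 2184 genes with any match the difference was −0.00801 (exact permutation p = 0.657), and camera called neither group. MEIS1, E2F2 and PALD1 each carry the 8-base match. Without 1 library MEIS1 reached an adjusted p of 0.127, PALD1 0.102 and E2F2 0.0564.

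**Figure D4:**
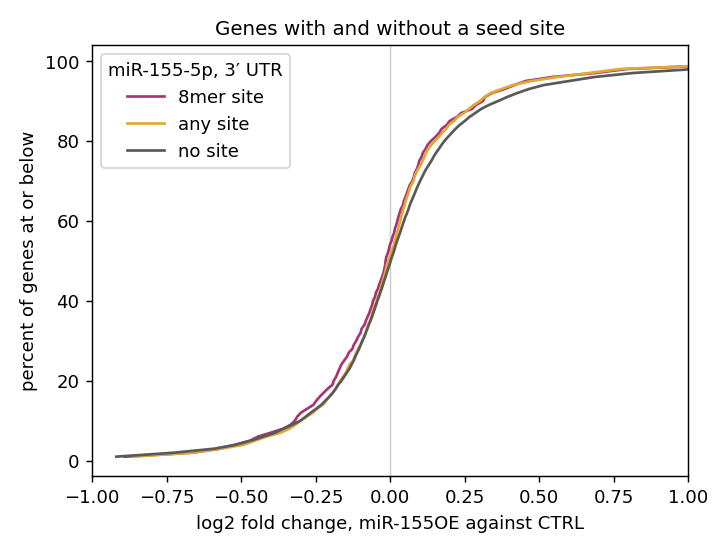
Cumulative percent of genes (vertical axis) by log2 fold change (horizontal axis) for genes with an 8-base miR-155-5p seed match in the 3′ UTR (579 genes), with any match (2184) and with none (10323). The medians lie at −0.02, −0.01 and 0.00, and to the right of 0 the curve of genes with no match lies lowest.

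Of 24 tested S-phase genes MCM4 rose and 23 did not pass, and TYMS, thymidylate synthase, fell both adjusted over the list alone, where 1 rose and 1 fell, and in the blocked fit (log2 fold change −0.43 in each). Of 12 tested G2/M genes edgeR called 0, with 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom, while adjusted over the list alone CDC20 passed (0.87). In the blocked fit CDC20, an activator of the anaphase-promoting complex, rose (0.83, SE 0.15) and ECT2, an exchange factor of cytokinesis, fell (−0.46). The median of that list was 0.06, its mean −0.00282 and camera's direction down (adjusted p = 0.949). Of 14 tested mesenchymal genes CDH2, N-cadherin, fell from 0.658 ± 0.288 to 0.130 ± 0.0324 CPM (SD, n = 4 each) and 13 did not pass, and adjusted over the list alone 1 rose and 1 fell. Blocked by replicate number 2 rose and 4 fell, VIM among them (−1.25). Of 25 tested cholesterol synthesis genes the sterol isomerase EBP fell (−0.51, SE 0.12) and 24 did not pass, with 1 adjusted over the list alone, and with the replicate block 2 rose and 5 fell and camera called the list lower (adjusted p = 0.0352, and adjusted p = 0.656 with an estimated correlation). Of 28 tested immediate early genes BTG2 rose and 27 did not pass, with 1 adjusted over the list alone and 2 higher and 2 lower with the replicate block. Without 1 library the adjusted p of MCM4 reached 0.0865, of CDH2 0.0671, of EBP 0.125 and of BTG2 0.123.

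In 4 further lists edgeR called 0 genes over all genes. For 32 tested interferon genes 2 had an unadjusted p under 0.05, DESeq2 called 1 and voom 0, adjusted over the list alone 0 passed, and with the replicate block OAS3 (log2 fold change 0.41) and OASL (21.5 ± 5.84 CPM in CTRL, 52.8 ± 32.4 CPM in miR-155OE, SD, n = 4 each) rose. For 28 tested unfolded protein and stress genes (median 0.00913, mean −0.00855, camera direction down) these counts were 3, 1, 0 and 0, and with the replicate block ATF3 fell (−0.33). For 18 tested antigen presentation genes they were 1, 0, 0 and 0, and HLA-C, which shares reads with near-identical genes, fell with the replicate block (−0.50). For 9 tested genes of simple and columnar epithelium they were 1, 0, 0 and 0, and with the replicate block the keratins KRT18 (−0.28) and KRT19 (−0.78) fell and camera called the list lower (adjusted p = 0.0419, and adjusted p = 0.634 with an estimated correlation).

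Markers of other cell types and of RNA quality were compared in the same way. Of 4 tested immune cell genes edgeR called 0 over all genes, with 3 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by voom, and 2 rose adjusted over the list alone. CD14 rose with the replicate block (log2 fold change 0.44). Of 6 tested endothelial, neural and melanocyte genes 0 passed by edgeR, DESeq2 or voom, at an unadjusted p under 0.05 or adjusted over the list alone. The 13 mitochondrially encoded genes likewise gave 0 by each of these, and with the replicate block MT-CYB fell (−0.31) and camera called the list lower (adjusted p = 0.0061, and adjusted p = 0.656 with an estimated correlation). Of 30 ribosomal protein genes RPL7 rose and 29 did not pass, with 1 adjusted over the list alone, and without 1 library RPL7 reached an adjusted p of 0.0757.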

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

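The tests of a copy number change and of a general advance of squamous differentiation, and the resampling interval for the seed sites, were chosen only after the result was seen.

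In 11 of 203 groups of 4 values that were tested, 1 library lay far from the others, where chance gives about 1 in 20. In CTRL replicate 4, DSC1 stood at 23.8 CPM against 7.22 to 8.19 in the other CTRL libraries, DSG1 at 429 CPM against 276 to 292, and EBP at 47.4 CPM against 51.9 to 52.6. In CTRL replicate 3, IL1B stood at 330 CPM against 221 to 233, TNFRSF10B at 167 CPM against 142 to 146, CNN1 at 0.439 CPM against 0.116 to 0.155, and VWF at 1.49 CPM against 2.08 to 2.19. In CTRL replicate 2, CHP2 stood at 1.10 CPM against 0.148 to 0.284. In miR-155OE replicate 3, PLD5 stood at 0.471 CPM against 0.848 to 0.901 in the other miR-155OE libraries and CDC20 at 10.8 CPM against 5.23 to 6.13. In miR-155OE replicate 4, CDH2 stood at 0.0821 CPM against at least 0.140.

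Genes of 8p were lower and genes of 8q higher in miR-155OE. Sets of genes from other chromosomes matched on GC content, transcript length and mean expression reached the 8p median in 0 of 10000 draws, which argues against these properties as the source. The 93 8p genes with no miR-155-5p seed match had a median log2 fold change of −0.38 (resampling interval −0.45 to −0.31), which argues against direct repression as the cause. A change in copy number of whole arms in part of the miR-155OE cells may account for it: the less and the more expressed parts of the 8p genes fell alike, at −0.39 and −0.36. That 97.6% of the 8p genes were lower restates the pattern and does not bear on its cause. DNA was not measured, and whether such a change arose by chance in the overexpressing line or is tied to the microRNA was not tested.

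KRT1, DSC1 and DSG1 were higher in miR-155OE. With every library thinned to 33.4 M (mega) counts, the highest adjusted p of the 3 genes by edgeR was 0.0186. With upper-quartile factors it was 0.0199. Neither setting could have removed rises of this size, so they do not decide on library size or a few abundant genes. Library totals overlapped between the groups. The median log2 fold change over genes was −0.00628 with TMM and −0.0152 with upper-quartile factors. With the replicate block, which rests on pairs taken from the library numbers, 18 members of the squamous list rose and 13 fell, which argues against a rise of the list as a whole. The bound for this test was set after these values were seen. On group alone 3 rose and 2 fell over all genes, which does not decide the question. An effect of the microRNA and a difference between the cell lines that came with its delivery stay open, since all 4 miR-155OE libraries carry the label of 1 stable line. KRT1 stood at 6628, 2677, 9619 and 6404 CPM in miR-155OE replicates 1 to 4, whose 8p medians were −0.49, −0.21, −0.58 and −0.28. KRT1 and DSG1 thus ranked as the 8p fall did, whereas DSC1 did not. The ranking was not tested, and the chromosome 8 change cannot be told apart from the microRNA in this design.

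Genes with an 8-base miR-155-5p seed match had a median log2 fold change that differed by −0.0170 from that of genes with none (resampling interval −0.029 to −0.00231; exact permutation test over libraries, two-sided, p = 0.229). For the 1464 genes with the 7-base match, with or without a following A, the difference from all other genes was −0.0139, and 6 of 419 scrambled heptamers were as low. The genes holding those heptamers were not matched on UTR length or GC content. Of the sets of site-less genes matched on UTR length and GC content, 97 of 10000 were as low as the genes with the 8-base match, and with mean expression matched too 45 of 10000. Matching did not reduce the difference (−0.0183, and −0.0196 with expression), which argues against UTR length and GC content as the whole source, although the 97 sets did not reach the bound set beforehand. A difference above −0.02 was set beforehand to count against repression, and −0.0170 meets this. The resampling interval, chosen after the result and drawn over genes that are not independent, spans that bound. Camera did not call the shift, whereas few scrambled heptamers were as low, so repression this small stays unsettled.

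On group alone, 8 splits of the libraries part all 4 pairs, too few for a share under 0.05: the real one called 488 genes and the highest other 0 by edgeR (999 at an unadjusted p under 0.05). The other splits keep some same-numbered libraries together: over all 35, 1 called as many, the real one, and the highest other, CTRL replicates 1, 2 and 3 with miR-155OE replicate 2, called 219. At an unadjusted p under 0.05 that split gave more genes than the real one, 3134 against 2925. CTRL replicates 1, 2 and 3 and miR-155OE replicate 2 were the lowest libraries on PC1. Blocked by replicate number, the real split called 1908 genes and the highest other 0 by edgeR (1155 at an unadjusted p under 0.05), again over 8 splits.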

How the results depend on the processing

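The alternatives without chromosome 8 genes, with miR-155-3p sites and with an estimated correlation under the replicate block were chosen after seeing the data. Counts are given as all genes past FDR 0.05, then in brackets genes higher in miR-155OE and genes lower in miR-155OE. The count of 488 (329 and 159) was within 1.5 times under DESeq2 size factors (517), upper-quartile factors (484), library totals (483), a filter of CPM of at least 1 (490), protein-coding genes alone (443) and limma-voom (503). Of the 50 named calls, some were lost there: 3 under upper-quartile factors (MEIS1 log2 fold change, adjusted p = 0.0505; EBP log2 fold change, 0.0501; BTG2 log2 fold change, 0.0505), 4 under library totals (MEIS1, 0.0581; EBP, 0.0614; KRT78 log2 fold change, 0.0541; IL18 log2 fold change, 0.0541), 1 of 47 under the CPM filter (MEIS1, 0.0508) and 1 under limma-voom (NELL2 log2 fold change, 0.112). The count was 927 (619 and 308) with no low-count filter and 1200 (769 and 431) by DESeq2. The cause was not tested. Of 44 named genes not called, 1 passed under DESeq2 size factors, 1 under limma-voom, 9 with no low-count filter and 13 by DESeq2, each in the same direction. Stricter thresholds gave fewer by construction: 81 (64 and 17) at a false discovery rate of 0.01, 167 (125 and 42) with an absolute log2 fold change of at least 1, and 117 (92 and 25) tested against 1.2-fold. Without chromosome 8 genes 339 were called, 244 higher and 95 lower.

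With the replicate block, which pairs same-numbered libraries, the count was 1908 (1125 and 783), CLDN7 passed (−0.66), and 8 gene lists were called by camera (0 with an estimated correlation, and 2 there at an unadjusted p under 0.05). Of the 50 named calls all 50 passed, 22 of the 44 named genes not called on group alone passed too, and the block changed no other call of a named gene. MIR155HG had 0 reads and gave no fold under any alternative.

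Leaving out 1 library gave 125 to 1274 genes past FDR 0.05, with 98 to 750 genes higher in miR-155OE and 25 to 524 genes lower in miR-155OE. The counts higher and lower were 121 and 35 without CTRL replicate 1, 159 and 44 without CTRL replicate 2, 98 and 31 without CTRL replicate 3, 305 and 94 without CTRL replicate 4, 100 and 25 without miR-155OE replicate 1, 750 and 524 without miR-155OE replicate 2, 135 and 38 without miR-155OE replicate 3, and 233 and 88 without miR-155OE replicate 4. Leaving out a number in both groups gave 26 genes (18 and 8) for number 1, 733 (455 and 278) for number 2, 47 (35 and 12) for number 3 and 235 (191 and 44) for number 4. Fewer libraries lower the power. Why leaving out miR-155OE replicate 2, the lowest of its group on PC1, raised the count was not tested. Of the 50 named calls, 22 passed in all 8 fits that left out 1 library. The others were lost in some: 24 without CTRL replicate 1, 18 without CTRL replicate 2, 26 without CTRL replicate 3, 10 without CTRL replicate 4, 24 without miR-155OE replicate 1, 21 without miR-155OE replicate 3, 13 without miR-155OE replicate 4 and 0 by edgeR without miR-155OE replicate 2.

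The CLDN7 log2 fold change stayed below 0 in every fit, from −1.11 without miR-155OE replicate 2 to −0.22 without CTRL replicate 2, and passed only with the block (edgeR adjusted p elsewhere 0.0537 to 0.833). The HIF1A log2 fold change ranged from −0.0861 without CTRL replicate 2 to 0.0388 without CTRL replicate 4, and was above 0 also without CTRL replicate 3 (0.02), miR-155OE replicate 1 (0.00428) or miR-155OE replicate 2 (0.02) and without number 4 of both groups (0.00946), never past the threshold.

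Camera called 2 lists, and 2 to 6 with 1 library left out: 4 without CTRL replicate 1, 4 without CTRL replicate 3, 3 without CTRL replicate 4 and 6 without miR-155OE replicate 2. With an estimated correlation it called 0 (2 at an unadjusted p under 0.05), likewise 0 with that correlation and the replicate block (2 unadjusted), and fry called 1. The cause was not tested. For miR-155 seed-site genes, median log2 fold change minus that of genes with no site was −0.00801 and ranged from −0.0176 without CTRL replicate 2 to 0.00351 without CTRL replicate 3, and was 0.00207 in UTRs shorter than the median, −0.00763 for miR-155-3p sites and −0.00887 without chromosome 8 genes.

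At 33.4 to 52.7 M (mega) counts per library, genes under 0.0569 to 0.0897 CPM could not be told from 0. Thinned to 33.4 M, 471 genes were called, 448 of them shared.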

Other observations

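The tests of the epidermal and mucosal lists and of the chromosome 8 arithmetic were chosen only after the result that prompted them was seen, and the permutation test of the list scores after their first result.

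Genes of epidermal cornification and of moist squamous mucosa were compared in a pair of lists, each tested without the members whose values had already been seen. Of 25 epidermal genes tested, 18 rose with the replicate block and 7 did not pass, with a median log2 fold change of 0.88. On group alone 5 rose. The risers included the cornification protease ASPRV1 (1.86, SE 0.28), the late envelope protein LCE1E (1.62, SE 0.28), the interleukin IL37 (1.28, SE 0.18) and the lipase LIPM (0.95, SE 0.07). Of 19 mucosal genes tested, 8 fell with the replicate block and 11 did not pass, with a median of −0.45. On group alone edgeR called 0 of them. Those that fell included PSCA (−1.67, SE 0.27), which lies on chromosome 8, the airway and esophageal proteases TMPRSS11D (−1.26, SE 0.29) and TMPRSS11E (−1.26, SE 0.23), and the foregut transcription factor PAX9 (−0.71, SE 0.14).

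A shift from a mucosal to an epidermal type of squamous differentiation may account for these changes, as a hypothesis found and tested on the same libraries. Camera with the replicate block gave p = 2.85e-23 for the epidermal list and p = 1.00e-06 for the mucosal list, and with an estimated correlation p = 0.0380 and p = 0.126. The epidermal median exceeded the mucosal median in 4 of 4 pairs, by 1.41, 1.11, 2.04 and 0.64 on the log2 scale (median 1.26). Per library, the difference was −0.00772 ± 0.254 in CTRL and 1.25 ± 0.877 in miR-155OE (SD, n = 4 each; exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allows). Whether the microRNA or another property of the stable line underlies the shift was not tested.

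If 1 of 2 copies of 8p were lost and 1 copy of 8q gained in the same cells, the 8p median of a library would set the share of such cells and so its 8q median. The 8p medians of miR-155OE replicates 1 to 4 give shares of 57.7%, 26.6%, 66.3% and 34.8% and predict 8q medians of 0.37, 0.18, 0.41 and 0.23. The observed medians were 0.32, 0.17, 0.41 and 0.22, and the largest departure was 0.0414 on the log2 scale. An isochromosome of 8q, or separate changes of both arms, in part of the cells is therefore a candidate explanation, which RNA alone cannot settle.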
